A study of Mus musculus with 16 samples.

How the data were processed

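Livers of male and female mice with floxed Matr3, with or without Cre recombinase under the albumin promoter, were profiled by RNA sequencing. RNA was extracted with TRIzol and directional poly(A) libraries were made by Novogene, per the labels' protocols. The authors deposited 1 table of counts per gene for each sex, with Ensembl gene identifiers and 8 libraries each, and the build is mm10 per the submitters' processing notes. The program used for alignment or counting and its strand setting are not in the sources used here. The deposited values were whole-number counts and were used as given. The tables held 24623 gene identifiers for males and 24840 for females, 23167 of them in both. Gene symbols came from a reference annotation, and 26 identifiers in males (0.0289% of counts) and 28 in females (0.0349% of counts) had none. The sum of the table in each library lay between 30495505 and 36496193. Intervals and floors cover counting error only.

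Groups were taken from the labels. Each sex was fitted alone, and a fit of all 16 libraries over the identifiers in both tables gave the effect over both sexes, the difference of the effects and the difference between floxed females and males. Genes were filtered with filterByExpr (minimum count 10, minimum total 15), scaled by TMM and tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Means and SDs are of TMM-scaled CPM, and log2 values for ranking used a prior count of 2. Matr3 was also tested with an exact permutation test in each sex. The overlap of the sexes was tested with Fisher's exact test.

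The comparisons, the rule for naming genes, the gene lists and all alternatives except those said to be added were chosen before the data were examined. Named genes were the 10 largest log2 fold changes in each direction per sex among called genes with a mean log2 CPM of at least 1 and no overlap between the groups. They were 5 in each direction for the difference of the effects and for floxed females against males, and the 10 smallest adjusted p besides Matr3 for the effect over both sexes. Predicted and clone-named gene models were counted and not named, and some genes that these rules name are not reported here. They made up 20 of the genes called in males and 128 of those called in females. For each list described, up to 4 members with the smallest p are given. Which lists to describe was decided after the list results were seen.

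There were 54 gene lists. Those with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, then with an estimated correlation and with fry. At the preset, 18 of 53 lists were called in males, 32 in females and 33 for the difference of the effects. With an estimated correlation 3, 0 and 1 were called.

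Alternatives were DESeq2 1.42.0, limma-voom, median-of-ratios and upper quartile scaling, no filter, a filter of 1 CPM in 4 libraries, robust dispersion, a log2 fold change of at least 1 in size, 1 surrogate variable from sva 3.50.0, the 16-library fit, omission of male floxed 1 and 2 (whose mouse numbers are 2710 and 2711), a block for the replicate number, and omission of each library in turn. Library totals and the joint omission of female floxed 4 and female LKO 7 were added after the data were seen. Replicate libraries were checked for copies. Within a group the smallest chi-square per degree of freedom between any pair was 13.7, and the lowest Spearman correlation was 0.983.

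The procedure was tested on simulated counts, drawn independently for each gene with the same dispersion for all genes. The simulation held no structure among libraries, so its rates need not hold for the real data. Of the calls, 4.22% were false for males (15405 genes), 5.26% for females (15481 genes) and 4.20% for the difference of the effects (15926 genes). Changes of 2-fold were recovered in 91.0%, 89.6% and 68.7% of genes, and changes of 1.5-fold in 49.3%, 28.4% and 5.97%.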

Results

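Poly(A) RNA was sequenced from the livers of 16 mice on a diet with 60% of its energy from fat. The diet began at 7 weeks of age and lasted 16 weeks, and tissue was taken after a fast of 12 hours. Matrin-3, encoded by Matr3, is an RNA-binding protein of the nuclear matrix. Mice carrying floxed Matr3 alleles were compared with mice, littermates per the labels, in which Cre recombinase driven by the albumin promoter deleted the gene in the liver (LKO). There were 4 male floxed, 4 male LKO, 4 female floxed and 4 female LKO mice, with 1 library each. The mouse numbers of male floxed 1 and 2 lie apart from those of all the other mice, and whether these animals were littermates of the LKO males could not be checked. The libraries held between 30495505 and 36496193 counts assigned to genes.

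The deleted gene was lower in every LKO library than in every floxed library of the same sex. Matr3 (ENSMUSG00000037236; mm10 chromosome 18, 35562138 to 35593835, plus strand) measured 57.1 ± 3.66 CPM (counts scaled to library size) in male floxed and 35.0 ± 1.51 CPM in male LKO livers (SD, n = 4 each, 61.3% of the floxed mean; exact permutation p = 0.0286, two-sided). The floxed males 1 to 4 had 55.3, 52.9, 60.9 and 59.4 CPM, and the LKO males 5 to 8 had 33.6, 36.5, 36.2 and 33.9 CPM. In females Matr3 measured 58.9 ± 5.10 CPM in floxed and 38.5 ± 1.40 CPM in LKO livers (SD, n = 4 each, 65.4% of the floxed mean; exact permutation p = 0.0286, two-sided). Floxed females 1 to 4 had 52.9, 64.7, 56.8 and 61.0 CPM, and LKO females 5 to 8 had 40.3, 37.1, 37.8 and 38.8 CPM. An exact p of 0.0286 is the smallest that 70 regroupings of 4 and 4 libraries allow. The edgeR log2 fold change of Matr3 was -0.71 (SE 0.06, adjusted p = 0.000807) in males and -0.61 (SE 0.08, adjusted p = 0.00437) in females. Counts were available per gene, so reads from deleted and retained exons could not be separated.

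**Figure D1:**
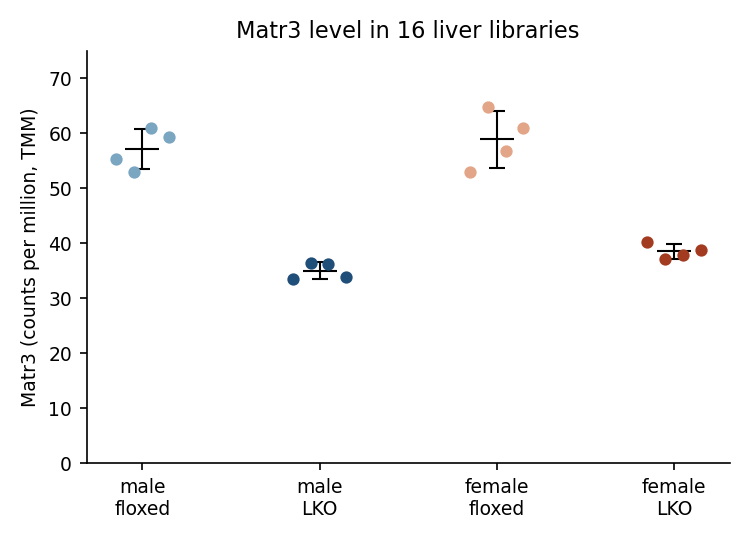
Matr3 level in TMM-scaled CPM (y axis) in each of the 16 libraries (points), with the group mean and SD (black bars, n = 4). The LKO libraries lie between 33.6 and 40.3 CPM and the floxed libraries between 52.9 and 64.7 CPM.

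The first comparison asked which liver transcripts differed between LKO and floxed males. Of 20 measured lipogenesis genes 5 rose in LKO males, and the smallest adjusted p belonged to a fall of Dcaf8, which encodes a substrate receptor of a cullin ubiquitin ligase. Dcaf8 went from 178 ± 8.25 to 77.8 ± 2.70 CPM (SD, n = 4 each), a log2 fold change of -1.20 (SE 0.06, edgeR adjusted p = 1.08e-05). Pklr, encoding liver pyruvate kinase, rose from 239 ± 22.8 to 489 ± 28.8 CPM, and Fasn, encoding fatty acid synthase, rose from 151 ± 16.4 to 264 ± 27.7 CPM (SD, n = 4). In the 16-library fit Pklr kept its call (edgeR adjusted p = 0.00397) and Fasn did not (edgeR adjusted p = 0.206). That fit estimates the spread of each gene over both sexes, and Fasn lay between 173 and 397 CPM in floxed females. In all, 160 of 15355 genes tested passed an edgeR adjusted p of 0.05, 81 higher and 79 lower.

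Of the genes with the largest rise in males, Pls1 (an actin-bundling plastin of epithelial cells) had a log2 fold change of 2.42, A4gnt (a glycosyltransferase of mucin-type glycans) 2.25, Prss8 (the serine protease prostasin) 1.75, Slc39a5 (a zinc importer) 1.62 and Pdlim2 1.24. Of those with the largest fall, Dsg1c (a desmosomal cadherin) had a log2 fold change of -1.47, Ripor2 -1.38 and Lrit2 -1.31. Each of these 8 calls held without any 1 of the 8 libraries. The call of Dcaf8 held likewise, and the remaining named genes lost their call without at least 1 library. Among these, Cyp2a4 rose by 2.25 and missed the threshold without floxed 3, LKO 5 or LKO 6, with edgeR adjusted p of 0.0565, 0.0615 and 0.0548, and with robust dispersion (0.104). Gprc5b rose by 1.76 and reached an edgeR adjusted p of 0.0506 without LKO 5. Corin (1.99) missed it without floxed 1, floxed 4 or any 1 of LKO 5 to 8, with edgeR adjusted p up to 0.0906. Mas1 (1.23) missed it without floxed 1, floxed 2 or any 1 of LKO 5 to 8 (up to 0.0987), without floxed 1 and 2 together (0.0707) and in the 16-library fit (0.284). Among those lower, Cyp2c54 (-1.88), Zfp979 (-1.71) and Zfp982 (-1.38) missed it without any 1 of LKO 5 to 8, with edgeR adjusted p up to 0.0967, 0.0623 and 0.0621, as did Cyp2c54 with robust dispersion (0.122) and Zfp982 in the 16-library fit (0.132). Serpina1e (-1.54) missed it without floxed 2, floxed 3, LKO 5, LKO 7 or LKO 8 (up to 0.121), without floxed 1 and 2 together (0.0677), with robust dispersion (0.145) and in the 16-library fit (0.325). Hnf4aos (-1.29) missed it without floxed 4 or any 1 of LKO 5 to 8 (up to 0.108) and with limma-voom (0.07). Sdr9c7 (-1.09) missed it without floxed 1, 2 or 3 or any 1 of LKO 5 to 8 (up to 0.155), without floxed 1 and 2 together (0.0844), with limma-voom (0.0686), robust dispersion (0.127) or library totals (0.0586) and with a filter of 1 CPM in 4 libraries (0.051). Cyp2a4, Cyp2c54 and Serpina1e have close paralogs with which reads can be shared, and Hnf4aos is antisense to Hnf4a, with the strand setting of the counting not given in the sources used here.

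The lipogenesis list, fixed in advance, had 5 of its 20 measured members higher and none lower in LKO males over all genes tested, and 15 higher and 1 lower adjusted over the list alone. Beside Pklr and Fasn, Elovl6, an elongase of fatty acids, rose by 0.94 (SE 0.12) and Me1, the cytosolic malic enzyme that supplies NADPH, by 0.59 (SE 0.08) on the log2 scale. In the 16-library fit Elovl6 missed the threshold (edgeR adjusted p = 0.0781) and Me1 kept its call. The list as a whole ranked higher than other genes (camera adjusted p = 6.45e-15, and adjusted p = 0.0101 with an estimated correlation, which became 0.0769 without male floxed 1 and 2). Lipid droplet genes had 2 of 18 members higher, and 6 adjusted over the list alone, among them Cidec, a droplet protein that promotes fusion (1.14), and Fitm2 (0.44), with Pparg at 0.58 and Cidea at 1.85 not passing (camera adjusted p = 1.27e-07, and adjusted p = 0.0356 with an estimated correlation). Cidec missed the threshold in the 16-library fit (edgeR adjusted p = 0.668) and without LKO 5, LKO 6 or LKO 8, with edgeR adjusted p up to 0.0552, and Fitm2 in the 16-library fit (0.266), without floxed 1 and 2 together (0.093) and without floxed 1, 2 or 3 or any 1 of LKO 5 to 8, with edgeR adjusted p up to 0.103. None of 7 adipocyte markers passed over all genes and 5 did adjusted over the list alone, with Cfd at 1.40, Lipe at 0.30, Cidea at 1.85 and Aqp7 at 1.51 (camera adjusted p = 5.9e-06, and adjusted p = 0.036 with an estimated correlation). Cidea is held by both of the last lists. The 2 lipid droplet calls became 1 without floxed 1, floxed 3 or LKO 7 and 0 without LKO 5, LKO 6 or LKO 8. Among adipocyte markers 1 was called without floxed 2.

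Cholesterol synthesis genes had no member called among 25 in males and 8 adjusted over the list alone, with Stard4 at 0.61, Hmgcs1 at 0.34 and Acat2 at 0.43 (camera adjusted p = 2.40e-08, but adjusted p = 0.722 with an estimated correlation). Without floxed 4 there were 2 called and without LKO 5 there was 1. Among glycolysis and glycogen genes Pklr rose and Gckr, the inhibitor of glucokinase, fell by 0.56 (SE 0.08) but missed the threshold in the 16-library fit (edgeR adjusted p = 0.0762), with Gys2 at 0.36 not passing (camera adjusted p = 9.85e-05, but adjusted p = 0.457 with an estimated correlation). Cytochrome P450 genes had 2 of 67 members higher and 4 lower, and 2 higher and 16 lower adjusted over the list alone, with Cyp2j9 at -0.96 among those lower, a call missed in the 16-library fit with an edgeR adjusted p of 0.247 (camera adjusted p = 0.0028, but adjusted p = 0.46 with an estimated correlation). Male-biased liver genes had 1 of 20 members lower, Susd4 at -0.64, and 3 adjusted over the list alone, with Cyp7b1 at -0.54 and Hsd3b5 at -2.64 not passing (camera adjusted p = 0.00423, but adjusted p = 0.771 with an estimated correlation). Susd4 missed the threshold in the 16-library fit (edgeR adjusted p = 0.208) and without floxed 3 or any 1 of the 4 LKO males, with edgeR adjusted p up to 0.105. The 6 cytochrome P450 calls became 3 without floxed 3, 1 without LKO 5 or LKO 6 and 2 without LKO 7 or LKO 8. Counts of called genes in males fell to 95 without floxed 3, 71 without LKO 5, 77 without LKO 6, 86 without LKO 7 and 69 without LKO 8. Of the 35 splits of the 8 male libraries, 22 gave at least as many camera calls as the 18 of the real one.

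The second comparison asked the same of females. In LKO females 20 of 25 acute-phase genes rose and 16 of 25 genes of cholesterol synthesis fell, though neither list was called with an estimated correlation (camera adjusted p = 0.31 and 0.41). Saa1 and Saa2, encoding the serum amyloid A proteins, rose 14.9-fold and 26.4-fold, and together took 2.03% of the counts in LKO against 0.117% in floxed livers. The sulfotransferase Sult2a1 fell from 284 ± 81.5 to 8.74 ± 5.0 CPM (SD, n = 4 each). Albumin transcripts made up 2.51% of counts in LKO and 4.85% in floxed females, with Alb at a log2 fold change of -0.88 (edgeR adjusted p = 0.0303). Mitochondrial transcripts took 2.68% (2.40% to 3.10%) in LKO and 3.81% (3.31% to 4.26%) in floxed females. Of 13 genes of the mitochondrial genome 5 were lower, and 6 adjusted over the list alone (camera adjusted p = 0.000126, but adjusted p = 0.413 with an estimated correlation). These 5 calls became 1 without floxed 2 or LKO 8 and 0 without floxed 1, floxed 3, LKO 5 or LKO 6. By edgeR 1433 of 15432 genes tested were called, 685 higher and 748 lower.

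Among the largest rises in females, Lepr, encoding the leptin receptor, went from 16.2 ± 13.3 to 219 ± 142 CPM and Igfbp1, an insulin-repressed binding protein of insulin-like growth factors, from 80.7 ± 21.4 to 793 ± 657 CPM (SD, n = 4 each). Igdcc4 had a log2 fold change of 4.05, Mup7 4.03, Scara5 3.79, Ppp1r3g (a regulator of glycogen synthesis) 3.43 and Dnaic1 3.36. The largest falls included Sult2a3 (-6.16), Sult2a2 (-5.01), the hydroxyacid oxidase gene Hao2 (-4.52), Car3 (-3.50), Cyp2a5 (-3.31) and Cyp2a22 (-3.17). Sult2a5 had 813 counts over the floxed libraries and 3 over the LKO libraries, a ratio of 268 with a 95% counting interval of 91.5 to 1304. Calls of these genes held without any 1 of the 8 female libraries, while those of Mup7 and Ppp1r3g were lost with limma-voom. Adcy1 (4.22) lost its call without floxed 1 (edgeR adjusted p = 0.0511) and with limma-voom, Cyp3a16 (-3.22) without floxed 1, LKO 6 or LKO 8 (up to 0.0657) and with robust dispersion (0.0607), and Cyp2g1 (-2.79) without floxed 1, floxed 2, LKO 5 or LKO 6 (up to 0.0682). The Sult2a, Mup, Saa, Cyp2a and Cyp3a families have near-identical members, so the split of reads between them is uncertain.

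**Figure D2:**
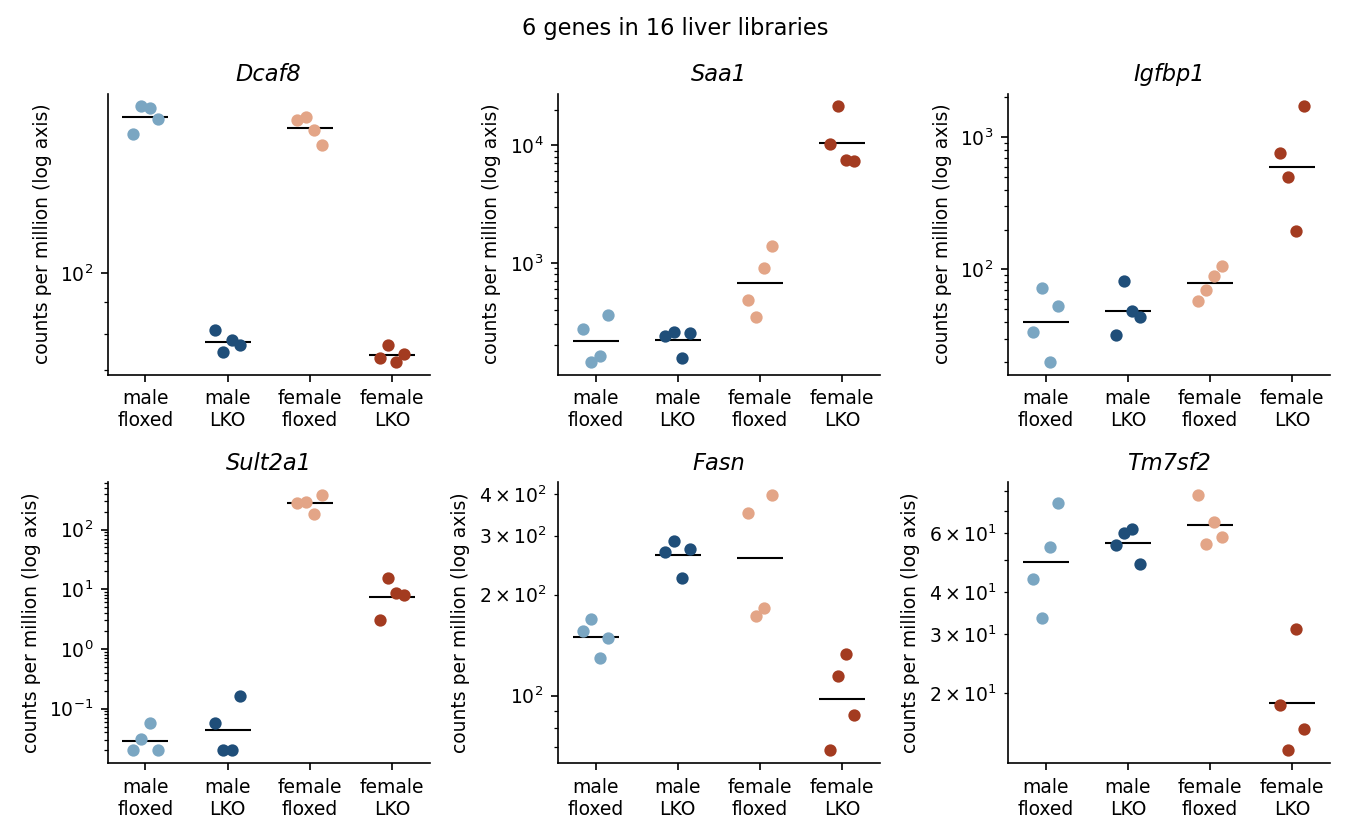
CPM on log axes for 6 genes in each library (points), with group geometric means (lines), TMM-scaled except for Sult2a1 in males, which uses library totals; values under 0.02 are drawn at 0.02. Dcaf8 separates genotypes in both sexes (178 against 77.8 CPM in males, 171 against 74.2 CPM in females), while Saa1, Igfbp1, Sult2a1 and Tm7sf2 separate them in females.

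Acute-phase genes, the liver's secretory response to inflammatory cytokines, had 20 of 25 members higher in LKO females and none lower, and 23 higher adjusted over the list alone. Saa1 and Saa2 led, followed by Socs3, a feedback inhibitor of cytokine signalling (1.19, SE 0.17), and Itih3 (1.22, SE 0.18). The list ranked above other genes by camera (adjusted p = 6.3e-17, but adjusted p = 0.31 with an estimated correlation). Neutrophil markers had none of 12 members called, by all genes or adjusted over the list alone, with Csf3r at 0.65, Cxcr2 at 1.28, Retnlg at 1.63 and Mmp9 at 0.90 (camera adjusted p = 0.00094, but adjusted p = 0.55 with an estimated correlation). Genes of endoplasmic reticulum stress and the integrated stress response had 8 of 27 members higher and 16 adjusted over the list alone, with Manf at 0.86 and Sdf2l1 at 1.44 (camera adjusted p = 2.1e-08, but adjusted p = 0.32 with an estimated correlation). The gluconeogenesis list, which also holds the insulin-repressed binding protein gene Igfbp1 (3.30), had 5 of 14 members higher, with Got1 at 1.39. Adjusted over the list alone, 7 were higher and 1 lower (camera adjusted p = 0.0036, but adjusted p = 0.31 with an estimated correlation). The 8 stress-response calls became 2 without floxed 1, 3 without floxed 2 or LKO 6, 4 without floxed 3, 5 without LKO 5 or LKO 8, 13 without floxed 4 and 14 without LKO 7. The 5 gluconeogenesis calls became 3 without floxed 3 and 2 without floxed 1, floxed 2, LKO 5, LKO 6 or LKO 8.

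Cholesterol synthesis genes had 16 of 25 members lower in LKO females and none higher, and 24 lower adjusted over the list alone. Tm7sf2, a sterol reductase, fell from 64.1 ± 9.97 to 19.6 ± 7.87 CPM (SD, n = 4) and Insig1, a sterol sensor, fell by 1.86 on the log2 scale, while Fdps (-2.77) lost its call without floxed 1, LKO 6 or LKO 8 (edgeR adjusted p up to 0.0536) and with limma-voom. By camera the list gave adjusted p = 2.4e-10, but adjusted p = 0.41 with an estimated correlation. Lipogenesis genes had 9 of 21 members lower, also 9 adjusted over the list alone, among them Srebf1, the transcription factor of the pathway, at 175 ± 34.3 against 58.4 ± 18.4 CPM, Acss2 (-0.89) and Thrsp (-2.78), while Acly (-0.88) lost its call without floxed 1 or LKO 5, with edgeR adjusted p up to 0.0541 (camera adjusted p = 5e-05, but adjusted p = 0.31 with an estimated correlation). Glycolysis and glycogen genes had 4 of 15 lower and 7 adjusted over the list alone, with Gckr at -1.10, Gbe1 at -0.49 and Ugp2 at -0.56 (camera adjusted p = 0.0015, but adjusted p = 0.31 with an estimated correlation). The 16 cholesterol synthesis calls became 3 without floxed 1 or LKO 6, 7 without LKO 5 and 5 without LKO 8. The 9 lipogenesis calls became 3 without floxed 1 or LKO 5 and 4 without LKO 8, and the 4 of glycolysis and glycogen became 8 without LKO 7.

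Female-biased liver genes had 14 of 25 members lower and 2 higher in LKO females, and 18 lower and 2 higher adjusted over the list alone. Sult2a1, Hao2 and Cyp2b9 (-0.85) fell while Sult3a1 rose by 1.44 (camera adjusted p = 8.2e-08, but adjusted p = 0.31 with an estimated correlation). Male-biased liver genes had 5 of 16 higher and 1 lower, the same numbers adjusted over the list alone, with Slco1a1 at 2.37, Mup20 at 1.86 and Ugt2b1 at -0.72 (camera adjusted p = 0.033, but adjusted p = 0.51 with an estimated correlation). Slco1a1 lost its call without floxed 1 (edgeR adjusted p = 0.0597), Mup20 without floxed 1 or floxed 2 (up to 0.0653) and Ugt2b1 without floxed 1 or LKO 5 (up to 0.0513). Drug-metabolism genes controlled by the receptors CAR and PXR had 10 of 22 lower and 2 higher, and 15 lower and 2 higher adjusted over the list alone, including Nr1i3, which encodes CAR itself (-1.01), and the carboxylesterase Ces2c (-1.82) (camera adjusted p = 2.3e-06, but adjusted p = 0.31 with an estimated correlation). Sinusoidal endothelial markers had 11 of 17 lower and 12 adjusted over the list alone, with Oit3 at -1.0 and Fcgr2b at -0.97 (camera adjusted p = 1.6e-07, but adjusted p = 0.31 with an estimated correlation). Female-biased calls became 6 lower and 1 higher without floxed 1, and 7 lower and 1 higher without LKO 6 or LKO 8. Male-biased calls became 1 without floxed 1 and 3 without floxed 2 or LKO 5. The 12 calls under CAR and PXR became 3 without floxed 1, 4 without floxed 2, 5 without LKO 5 and 7 without LKO 6. The 11 sinusoidal calls became 2 without floxed 1, 3 without floxed 2, LKO 5 or LKO 6, 6 without floxed 3 and 4 without LKO 8.

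Within the female groups, floxed 4 and LKO 7 lay nearest to the other genotype on the first principal component, at -7.50 and 6.86, where the other floxed females lay between -29.7 and -25.6 and the other LKO females between 24.6 and 31.0. Without both, an alternative added after the data were seen, 3028 genes were called, and 1337 of the 1433 were called in both fits, all in the same direction. These libraries were picked for lying nearest to the other genotype, and both fits share the remaining libraries. The rise in calls and the agreement are therefore no independent support. Single omissions gave 396 calls without floxed 1, 475 without floxed 2, 666 without floxed 3, 509 without LKO 5, 622 without LKO 6, 2300 without LKO 7 and 685 without LKO 8. A surrogate variable as covariate left 16 calls, and the genotype groups explained 66.4% of that variable. Of the genes called in females and checked under it, Sult2a1, Sult2a2, Sult2a3, Sult2a5, Sult3a1 and Mup20 kept their calls. With library totals in place of TMM, 449 genes were higher and 1240 lower.

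**Figure D3:**
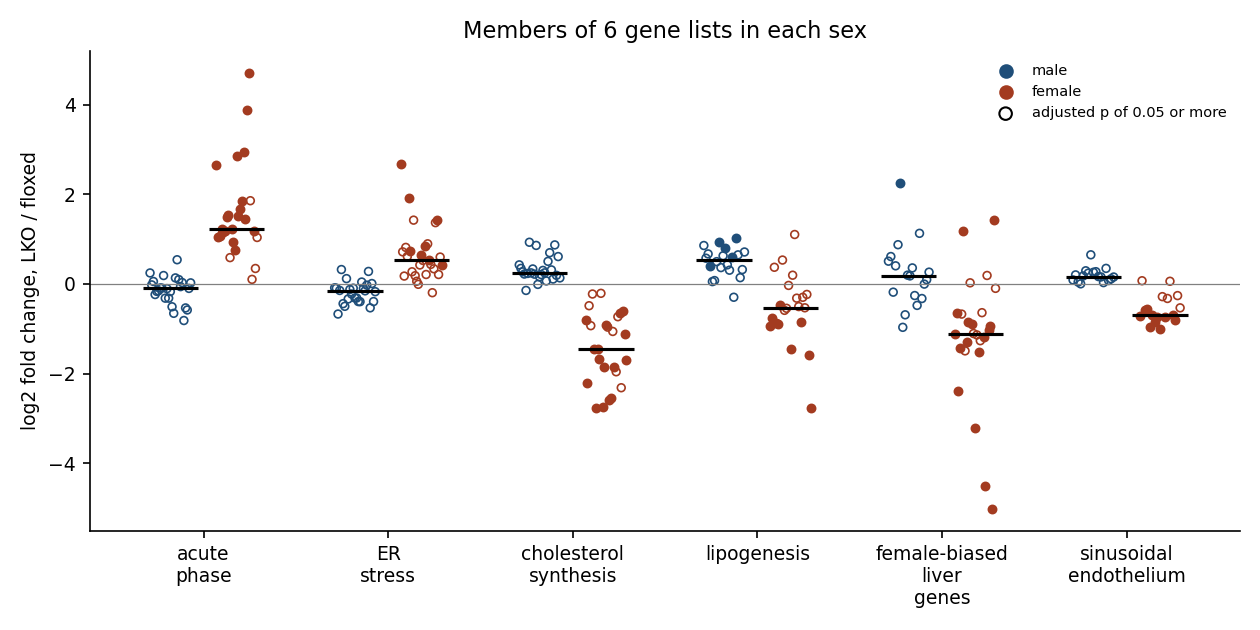
The edgeR log2 fold changes (y axis) of the measured members of 6 gene lists in males (blue) and females (red), filled where the adjusted p is under 0.05, with list medians as black lines. The lipogenesis medians are 0.54 in males and -0.53 in females, and 20 acute-phase genes passed in females.

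Whether both sexes changed the same genes was tested over the 14921 genes measured in each. A set of 41 genes was lower in both, against 3.70 expected for independent lists (Fisher's exact p = 4.80e-34, two-sided), and 15 were higher in both, against 3.34 expected (Fisher's exact p = 8.78e-07). Another 6 genes were higher in males and lower in females (3.70 expected), and 1 was lower in males and higher in females (3.34 expected). Matr3, the deleted gene, is among the 41. Fisher's test takes genes as independent, which they are not, so its p does not measure the spread between mice. The log2 fold changes correlated weakly across genes, with r = 0.124 and Spearman's rho = 0.103, genes not being independent replicates. The number of genes called in the same direction, 56, became 36 without male LKO 5, 37 without male LKO 7 and 36 without male LKO 8.

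**Figure D4:**
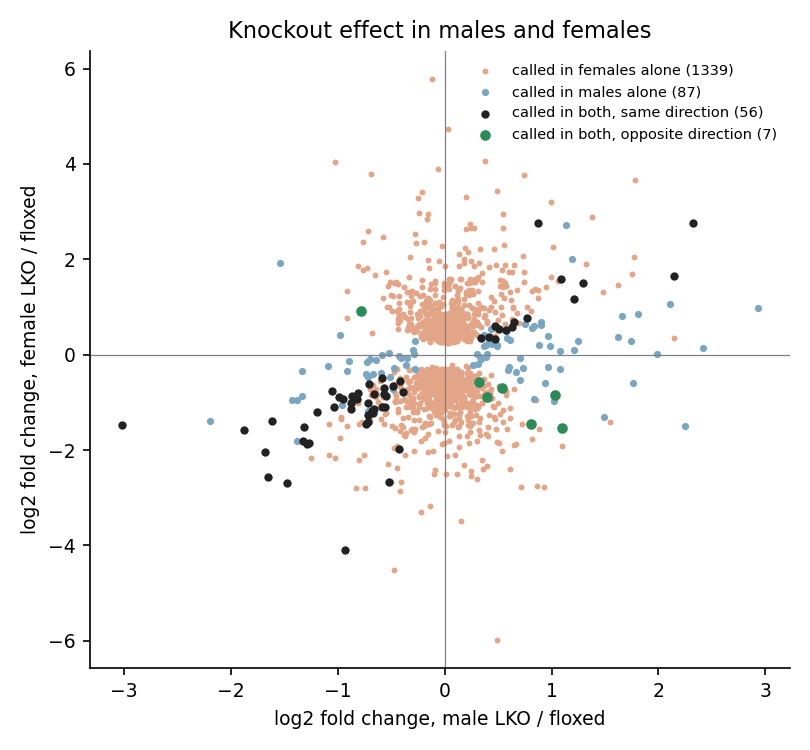
Log2 fold changes of LKO over floxed in males (x axis) and females (y axis) for genes called in either sex (points). Among these, 1339 were called in females alone, 87 in males alone, 56 in both with the same direction and 7 in both with opposite directions.

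Averaged over both sexes in a fit of all 16 libraries, 1379 of 16126 genes were called by edgeR, 653 higher and 726 lower. Dcaf8 fell by 1.20 on the log2 scale (SE 0.04, edgeR adjusted p = 2.39e-11). Next by adjusted p came Arsk, a lysosomal sulfatase (-0.95), the plasma carboxypeptidase Cpq (-0.57), the endocytic adaptor Eps15l1 (0.54), the DNA repair methyltransferase Mgmt (-0.94), Asb3 (-0.94), the inflammasome sensor Nlrp6 (-0.87), the DNA helicase Ascc3 (-0.90), Oxr1 (-0.54) and Sugct (-0.99). Every 1 of these 10 genes kept its call in all 27 alternative fits. Acute-phase genes had 15 of 25 members higher, and 17 adjusted over the list alone, with Saa2 at 2.38 and Crp at 0.57 (camera adjusted p = 4.7e-14, but adjusted p = 0.5 with an estimated correlation). No acute-phase gene was called higher in LKO males alone, and the log2 effect on Saa2 was 4.69 larger in females. This average need not describe either sex. The count of called genes was 860 without male floxed 3, 788 without male LKO 6, 895 without male LKO 8, 820 without female floxed 2, 837 without female LKO 5 and 2252 without female LKO 7. Library totals gave 376 higher and 1079 lower.

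The test of the difference itself, female minus male LKO effect, called 713 of 16126 genes by edgeR, 318 with a more positive effect in females and 395 with a more negative one. The largest positive differences were in Mup7 (5.05), Saa2 (4.69), Scara5 (4.48), Saa1 (3.96) and Igdcc4 (3.68), and the largest negative ones in Hao2 (-4.04), Cyp2a4 (-3.74), Fdps (-3.70), Car3 (-3.65) and Idi1 (-3.60). All but Igdcc4, which lost its call without male floxed 4 (edgeR adjusted p = 0.0521), held without any 1 library, while Mup7, Igdcc4 and Idi1 lost theirs with limma-voom, Igdcc4 and Idi1 without male floxed 1 and 2, and Mup7 and Igdcc4 with a surrogate variable. Saa1 measured 234 ± 102 CPM in male floxed and 225 ± 48.0 CPM in male LKO livers (SD, n = 4), while Cyp2a4 rose in males and stood at -1.49 in females (edgeR adjusted p = 0.0544).

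Acute-phase genes had the smallest camera p for the difference at the preset correlation, with 17 of 25 members more positive in females and 23 adjusted over the list alone, including Itih3 (1.54), Fgb (1.32) and Fga (1.48) (camera adjusted p = 2.3e-22, but adjusted p = 0.21 with an estimated correlation). Lipogenesis genes had 11 of 21 members more negative in females, and 13 adjusted over the list alone. Fasn differed by -2.26, Pklr by -1.88, Srebf1 by -1.90 and Acly by -1.28 (camera adjusted p = 4.2e-13, and adjusted p = 0.022 with an estimated correlation). Without male floxed 1 and 2 the latter became 0.0677. Cholesterol synthesis genes had 16 of 25 more negative and 23 adjusted over the list alone, with Stard4 at -1.73 and Tm7sf2 at -1.84 (camera adjusted p = 1.1e-15, but adjusted p = 0.23 with an estimated correlation). Sinusoidal endothelial markers had 9 of 17 more negative and 12 adjusted over the list alone, with Oit3 at -1.26 (camera adjusted p = 5.5e-11, but adjusted p = 0.21 with an estimated correlation). Stress-response genes of the endoplasmic reticulum had 6 of 27 more positive and 12 adjusted over the list alone, with Xbp1 at 0.59 and Manf at 1.25 (camera adjusted p = 6.6e-09, but adjusted p = 0.21 with an estimated correlation). The 9 sinusoidal calls became 5 without male LKO 7, male LKO 8 or female LKO 5. The 6 stress-response calls became 3 without male LKO 5, 6 or 8 or female floxed 1 or 2, and 10 without female LKO 7; that of Xbp1 was lost with a replicate block or a surrogate variable and that of Manf with a surrogate variable. The count of genes with a difference was 459 without male LKO 5, 410 without male LKO 7, 426 without male LKO 8, 407 without female floxed 1, 464 without female floxed 2, 1134 without female floxed 4, 448 without female LKO 5 and 1435 without female LKO 7. Library totals gave 203 more positive and 698 more negative.

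Floxed females and males differed in the direction their labels state. Xist had 13346 to 18315 counts in the female libraries and 0 to 6 in the male ones, and Ddx3y (2129 to 2375 counts), Eif2s3y (1686 to 2142), Kdm5d (602 to 743) and Uty (393 to 507) were listed in the male table and not in the female one. All 23 measured female-biased liver genes were higher in floxed females (camera adjusted p = 2.5e-23, and adjusted p = 0.011 with an estimated correlation), and 19 of 20 male-biased genes were lower (camera adjusted p = 6.3e-17, but adjusted p = 0.057 with an estimated correlation), with the same counts adjusted over each list alone. Sult2a2 was higher in females by 11.85 on the log2 scale. Sult2a1 had 36880 counts over the female floxed libraries and 3 over the male ones (ratio 12429, 95% counting interval 4253 to 60274), Sult2a3 had 8211 against 1 (ratio 8302, 1490 to 327940) and Cyp3a41a 33388 against 1 (ratio 33757, 6058 to 1333400). Obp2a, with 1226 counts in floxed males and 0 in floxed females, was at least 404-fold higher in males against a floor of 3 counts over the group. Cyp4a12a had a log2 difference of -10.50, Mup7 -9.89 and Nat8f5 -7.08, and Cyp4a12b had 849 counts in males against 3 (ratio 280, 95.5 to 1360). By edgeR 3698 of 16126 genes were called, 1826 higher and 1872 lower in females, which became 2237 and 1483 with upper quartile scaling and 2460 and 1217 with library totals. Each sex was deposited as its own table, so sex and any effect of table cannot be separated here.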

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

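The counts of calls under other splits of the libraries, the tests of immune cell markers, of the Matr3 level against mislabelling and of GC content over all genes were chosen after the results they bear on were seen.

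Besides Matr3, 40 genes fell in both sexes, with a median genomic span of 53.7 kb against 21.4 kb in random sets matched on expression (percentile 99.99 of 10000). The set's median GC content of 45.1% lay at percentile 0.06 of the random sets, the outcome named in advance for a bias of GC content or length. In a test chosen afterwards, 3920 other genes of as low GC content shifted little. Their median log2 fold changes were -0.023 in males (quartiles -0.13 and 0.07) and -0.02 in females (quartiles -0.22 and 0.14). The set had -0.81 and -1.14 but was selected for its falls, so this contrast cannot exclude a GC bias. Genes higher in females alone had a median GC content of 51.6% (percentile 100). On the chromosome of Matr3 lay 1 of the 40 genes. Both groups carry the floxed alleles, so this count says nothing on linked variants. Variants near the Cre transgene were not tested. That matrin-3 acts on some long genes may be a hypothesis only (percentile 99.96 in sets matched on GC content as well): from the shortest to the longest quartile of span of all genes, the set included, 5, 14, 29 and 31 were called lower in males (17, 20, 20 and 24 higher) and 136, 162, 228 and 221 in females (166, 176, 178 and 165 higher), and the median span of genes lower in females alone lay at percentile 99.99 and that of genes lower in males alone at 87.97.

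Of 25 acute-phase genes 20 were called higher in LKO females and 0 in LKO males, where 1 was called lower without floxed 3 (in females camera adjusted p = 6.3e-17, but adjusted p = 0.31 with an estimated correlation). With the 50 most abundant genes left out of totals and scaling, 20 of 20 stayed called, the outcome named in advance against a few abundant genes. TMM already limits the weight of such genes, and their omission left the list median at 1.24. The test could thus hardly come out otherwise and decides nothing. The lowest floxed Matr3 level lay 12.6 CPM above the highest LKO level, which argues against swapped genotypes. Immune cells stay open: 1 of 63 markers of 4 immune cell lists was called higher and 0 lower, and neutrophil markers ranked higher by camera (adjusted p = 0.00094, but adjusted p = 0.55 with an estimated correlation). A test added afterwards found the median of these markers at 0.15 (SD 0.55) against 1.24 for acute-phase genes, so the markers rose less. Acute-phase genes are a liver response to cytokines, and immune markers need not rise as much. The test therefore cannot decide whether immune cells drove the rise. An inflammatory state of the LKO females may be another source, and was not tested apart from the genotype.

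Of the lipogenesis genes 5 of 20 were called higher in males and 9 of 21 lower in females (3 without female floxed 1 or LKO 5 and 4 without female LKO 8), with a median difference of -0.94. Among those called in both sexes, in opposite directions, were Fasn (log2 fold change 0.81 in males and -1.45 in females), Pklr (1.03 and -0.85) and Acly (0.40 and -0.88). The male call of Fasn was lost in the 16-library fit (edgeR adjusted p = 0.206). The female call of Pklr was lost without floxed 1, floxed 3, LKO 5, LKO 6 or LKO 8 (up to 0.0781). Over all genes, 6 were higher in males and lower in females, against 3.70 expected (Fisher's exact p = 0.274). In females the list gave a camera adjusted p of 0.31 with an estimated correlation. Without male floxed 1 and 2 the male median was 0.52, under other scalings the female median nearest to 0 was -0.53, and without any 1 library the difference nearest to 0 was -0.86. These argue against those mice, the scaling or any 1 library as the source of the medians, but with an estimated correlation the calls in males (camera adjusted p = 0.0769) and for the difference (0.0677) were lost without male floxed 1 and 2. A sex-dependent response to the loss of matrin-3 is a hypothesis. Sex is confounded with the deposited table. An effect of table shared by both genotypes cancels in the difference, but one that differs between genotypes cannot be told apart from sex.

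Other lists also differed between the sexes by the test of the difference. The medians were 1.54 for acute-phase genes, -1.71 for cholesterol synthesis, -0.80 for sinusoidal endothelial markers, 0.77 for stress of the endoplasmic reticulum, -0.94 for female-biased liver genes and -0.51 for glycolysis and glycogen genes. With an estimated correlation the adjusted p of these lists lay between 0.19 and 0.23. In all, 713 genes differed.

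Among named genes the effect was more negative in females for Pls1 (-2.28), Cyp2a4 (-3.74), Gprc5b (-2.36), Prss8 (-1.45), Slc39a5 (-1.25), Hao2 (-4.04), Car3 (-3.65), Cyp2a5 (-3.08) and Cyp2a22 (-3.03). It was more positive for Serpina1e (3.46), Saa2 (4.69), Saa1 (3.96), Igdcc4 (3.68), Mup7 (5.05), Scara5 (4.48), Lepr (3.02) and Igfbp1 (3.10).

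Of 104 groups of 4 libraries examined for a distant library, 4 had one, and chance gives about 1 in 20. Sult2a3 was 57.3 CPM in female floxed 3, against 65.2 to 65.4 in the other floxed females. Car3 was 564 CPM in female floxed 4, against 1393 to 1594. Mitochondrial transcripts took 6.04% of the counts of male floxed 4, against 5.63% to 5.70%, and Alb took 4.58% of those of male floxed 1, against 5.49% to 5.63%.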

How the results depend on the processing

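Library totals and the joint omission of female floxed 4 and LKO 7 were added after the data were seen. The cause was not tested for any change below unless stated. With DESeq2 the genes called were 518 in males, 2415 in females and 1358 for the difference of effects. A log2 fold change of at least 1, which removes genes by construction, left 56 in males, 468 in females, 318 for the difference, 197 over both sexes and 896 between floxed groups. A surrogate variable left 16 in females, 163 for the difference and 151 over both sexes. The groups explained 66.4% of this variable in females and 51.1% for the difference and over both sexes, so it overlaps with the group differences themselves. The 16-library fit called 97 in males and 2854 in females. Without female floxed 4 and LKO 7, 3028 were called in females, 2030 for the difference and 2902 over both sexes. The difference had 2.4e+02 (rounded) without male floxed 1 and 2 and 468 with a replicate block.

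Without 1 library the count lay between 69 and 179 in males, 396 and 2300 in females, 407 and 1435 for the difference, 788 and 2252 over both sexes and 2874 and 3907 between floxed groups. Genes called in the same direction in both sexes (56) numbered 109 at an adjusted p of 0.1 and 162 with DESeq2, and 36 to 67 without 1 library. With an estimated correlation 3, 0 and 1 lists were called in males, females and the difference, and with fry 3, 17 and 16.

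The next counts cover called genes that were named or were among the first members of lists chosen for description (31 in males and 88 in females). For these, the omission of 1 library kept 175 of 248 calls checked in males, 542 of 704 in females, 507 of 528 for the difference and 160 of 160 over both sexes. Other settings, apart from the log2 fold change of at least 1, kept 316 of 341, 868 of 965, 373 of 396 and 110 of 110. Of all these 1 changed direction, Plin3 in females, at -0.012 with a surrogate variable. Matr3 in females reached an edgeR adjusted p of 0.158 with that variable.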

Other observations

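The counts under other splits were chosen after the results were seen. Circadian genes, the clock-controlled regulators of liver metabolism, had 4 of 19 members lower in LKO females, and 2 higher and 10 lower adjusted over the list alone (camera adjusted p = 0.00094, but adjusted p = 0.31 with an estimated correlation). Called members became 1 without floxed 1, floxed 2 or LKO 6, and 9 lower and 1 higher without LKO 7. Glucuronosyltransferase genes, which conjugate bilirubin and drugs, had 7 of 12 lower and 8 adjusted over the list alone (camera adjusted p = 1.1e-05, but adjusted p = 0.31 with an estimated correlation). These 7 became 0 without floxed 1 or LKO 5, 2 without floxed 2, 3 without floxed 3 or LKO 8 and 4 without LKO 6. Interferon-response genes had 4 of 35 lower and 5 adjusted over the list alone (camera adjusted p = 1.5e-05, but adjusted p = 0.55 with an estimated correlation). These 4 became 0 without floxed 1, 1 without floxed 2, floxed 3, LKO 5 or LKO 8, 2 without LKO 6 and 16 without LKO 7.

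None of 13 tested neighbours of Matr3 was called in males, where log2 fold changes were 0.29 for Slc23a1, 0.44 for Spata24, 0.52 for Prob1, -0.21 for Cxxc5, 0.10 for Ctnna1, -0.09 for Sil1, 1.03 for Mzb1, -0.97 for Egr1, 0.05 for Paip2, -0.08 for Dnajc18, 0.02 for Ube2d2a, -0.07 for Ecscr and 0.07 for Tmem173. In females Dnajc18 was called (0.54, edgeR adjusted p = 0.0333). The others in females were Ecscr at -0.40, Prob1 at 0.35, Spata24 at 0.56, Slc23a1 at 0.21, Tmem173 at 0.22, Ube2d2a at 0.07, Cxxc5 at 0.07, Mzb1 at 0.30, Ctnna1 at 0.05, Egr1 at -0.19, Paip2 at 0.0017 and Sil1 at 0.0002.

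The real split called the most genes in males (160 against 1 in the highest other split, 1 of 35 splits as large) and in females (1433 against 436, 1 of 35). With 35 splits, 1 of 35 is the smallest share possible. The split with 436 exchanges female floxed 4 with LKO 7, which points to a structure among these libraries. In a fit of the floxed libraries alone the real split also called the most (2863 against 1, 1 of 35). The real grouping led for the difference of effects (713 against 44, 1 of 100) and the effect over both sexes (1379 against 128, 1 of 100). The other regroupings left out any that kept the real grouping of either sex, so they cannot exclude chance there. Genes called in the same direction in both sexes numbered 56 against 9 (1 of 1225). Other splits called hardly any genes, apart from the female one with 436, so this count cannot exclude a chance overlap. For the number of lists called at the preset correlation the real split led by a narrow margin in females (32 against 29 in the highest other split, 1 of 35). The margin was as narrow for the difference (33 against 29, 1 of 100, from the same regroupings). It did not lead for the 18 lists in males, where 22 of 35 splits gave as many and the highest other gave 26. The other splits called 8 to 29 lists in females and likewise 8 to 29 for the difference, so the margin says nothing on any single list, and with an estimated correlation 0 lists were called in females and 1 for the difference.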
